A study of Homo sapiens with 18 samples.

How the data were processed

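DLD-1 and HT29 colorectal cancer cells were grown in 3 dimensions and left unirradiated or irradiated with 2 Gy, 10 Gy or 5 fractions of 2 Gy, and total RNA was taken 4 h after treatment, per the labels. Amplified RNA of unirradiated cells was labelled with Cy3 and that of irradiated cells with Cy5 on every array, per the labels' protocols, with no dye swap. The labels do not say whether arrays shared control RNA, and they call the 3 arrays of a group biological replicates. Each of the 18 array files held the mean and median intensity of every spot and of its local background in both channels, as deposited, and per the file headers these intensity values were extracted from the scans with ImaGene and were not normalized. A table of log2 values of the same arrays was deposited as the authors' processed values, with its processing not given in the sources used here. Set against each array's unnormalized log2 ratios of Cy5 over Cy3, its columns had positive slopes and correlations of 0.681 to 0.993, and column medians of -0.0036 to 0.0051. Its direction was therefore taken as irradiated over control and its centring as near 0, while its exact scale factor stayed unknown, and it served only as an alternative.

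An array held 45220 spots, of which 43118 were gene spots of 34127 probes and 153 were negative controls. Probes were named through RefSeq gene names by unversioned accession (25771), by symbol (2207) or by older symbol (499), and 5650 kept the name in the file. Mean spot signals were background-corrected with normexp (offset 50) and normalized within each array by loess, with control and quality-marked spots at weight 0, in limma 3.58.1 with statmod 1.5.0 and R 4.3.3. Spots with the extraction software's quality mark were left out. The mark fell on 30.6% of the gene spots in the brightest 10%, on 0.615% of the others and on 99.9% of saturated spots, which leaves out bright signals, and keeping those spots was run as an alternative. Spots of a probe were averaged. A probe was above background where its signal exceeded the mean of the negative controls by 2.6 SD, and 20691 probes were kept that were above background in at least 1 channel on all 3 arrays of at least 1 group. Of several probes of a gene the one with the highest mean intensity was used, which gave 16438 genes and other features with 5.17% of values missing. Among 3525 genes with several probes, 0 to 282 a comparison had probes passing in both directions.

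In total 51.1 to 72.6% of gene spots (median 58.6%) were above background in Cy3 and 42.9 to 65.3% (median 51.1%) in Cy5. Median Cy3 signals were 377 to 728 against 250 to 500 for negative controls, and median Cy5 signals 354 to 837 against 235 to 573. The number of arrays limits the precision. No pair of arrays had identical values, and the highest correlation of raw Cy5 values between arrays was 0.992.

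All 18 arrays in 6 groups were fitted together with limma's moderated linear model, 1 coefficient a group, with at least 2 values in each group compared, and genes passed at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. The comparisons were each group against its control, 10 Gy against 2 Gy and 5x2 Gy against 10 Gy within a line, and HT29 against DLD-1 at each treatment. The 25 gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, on members with a value in every group and missing values set to the group mean, with an estimated correlation and fry as alternatives. The groups, comparisons, tests, lists and most alternatives were fixed before the data were examined.

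The rule for named genes took, in each comparison, features with a gene symbol that passed, with the same sign on all 3 arrays or with no overlap between groups. Of these the 12 largest rises and the 12 largest falls, and up to 4 members of each list, could be named, as could CDKN1A, MDM2, GDF15, CCNB1 and PLK1 against control. The examples in the text were picked from these after their values were seen. Lists included the cell cycle, histones, DNA repair, interferon and MHC class I genes, NF-kB and immediate early genes, hypoxia, cholesterol synthesis, protein, oxidative and heat stress, apoptosis, autophagy, matrix and mesenchymal genes, stem cell and differentiation genes, oxidative phosphorylation, ribosomal proteins, ERBB ligands and metallothioneins. Markers of cells that the cultures should lack were reported as levels.

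The analysis was tested on simulated data in which 200 genes of a comparison were changed by known amounts. The simulated noise was independent between genes and arrays, without dye or slide effects. Calls among unchanged genes may therefore be more frequent in the real data. For 10 Gy against control in DLD-1, over 15647 genes, 65 of 67 genes changed 1.5-fold, 67 of 67 changed 2-fold and 66 of 66 changed 4-fold were called, with 8 of 15407 unchanged genes. For 10 Gy against 2 Gy in DLD-1, over 15395 genes, the calls were 55 of 67, 67 of 67 and 66 of 66, with 10 of 15155 unchanged genes. Another 40 genes, lowered together to test camera, are in neither count. Alternatives were no background subtraction, median centring, scale normalization between arrays, no filter or a strict filter on dim probes, the mean of all probes of a gene, only the arrays of the groups compared, the replicate number or the slide as a block, array weights, the deposited log2 values, Cy5 channels compared directly after Aquantile normalization, and leaving out each array. The 18 arrays lay on 5 slides, and DLD-1 5x2 Gy shared no slide with the other DLD-1 groups. HT29 5x2 Gy shared none with HT29 10 Gy. DLD-1 2 and 10 Gy shared a slide through replicate 3 of 2 Gy, HT29 2 and 10 Gy through replicate 1 of 2 Gy, and the lines at 5x2 Gy through replicate 3 of HT29, so fits with the slide as a fixed block or within a slide rest on 1 array of a group.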

Results

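Gene expression was measured in DLD-1 and HT29 cells, lines established from human colorectal carcinomas. Cells grown in 3 dimensions in a laminin-rich matrix received X-rays as 1 dose of 2 Gy, 1 dose of 10 Gy, or 5 fractions of 2 Gy (5x2 Gy), and RNA was taken 4 h after treatment. For 5x2 Gy the labels do not say whether the 4 h ran from the last fraction, nor when its unirradiated cultures were taken, so these ratios can also hold differences in culture time. Each of the 18 arrays carried irradiated RNA in Cy5 against unirradiated RNA of the same line in Cy3, with 3 arrays, called biological replicates in the labels, in each of the 6 groups. On an array, 42.9 to 65.3% of the gene spots were well above background in Cy5 and 51.1 to 72.6% in Cy3. Log2 ratios of arrays of a group correlated across genes with a median r of 0.729, against 0.523 for arrays of the same line and another treatment. Values are log2 ratios of irradiated over control RNA ± SE, from 3 arrays a group unless stated. Changes were tested with limma and Benjamini-Hochberg adjustment, and gene lists with camera, on the members that had a value in every group. Genes given as higher or lower passed at an adjusted p under 0.05 and had the same sign on all 3 arrays, or no overlap of the 3 and 3 arrays between groups, except CCNB1, PLK1, CDKN1A, MDM2 and GDF15, which were given against control in any case. The labels do not say whether replicates were separate cultures, and p-values measure the spread between these arrays, which may be technical.

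Because the control was always in Cy3, a ratio against control also holds any difference in how a probe takes up the dyes. Of 14792 genes tested in all 6 groups, 118 rose and 919 fell in every group, where 0.0704 and 2.55 would be so called if the groups were independent. The lowest of these was AQP6, an aquaporin gene, with -3.49 over the 6 groups and a range from -3.74 to -3.24. NID2, which encodes a basement membrane protein, had -2.16 over the 6 groups, and SLC22A7, an organic anion transporter gene, had -2.31. The mean over the groups took 70.8% of the sum of squares of the group means. For this reason each group was also set against the mean of the 6 groups, a comparison added after the data had been examined, in which a constant dye difference cancels, but which also depends on the other groups. Of 28 list calls against control, 11 passed in the same direction against that mean, 2 in the opposite direction and 15 did not pass, and 23 list tests passed only against the mean. With an estimated correlation 6 of the 11, 0 of the 2 and 2 of the 23 passed.

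**Figure D1:**
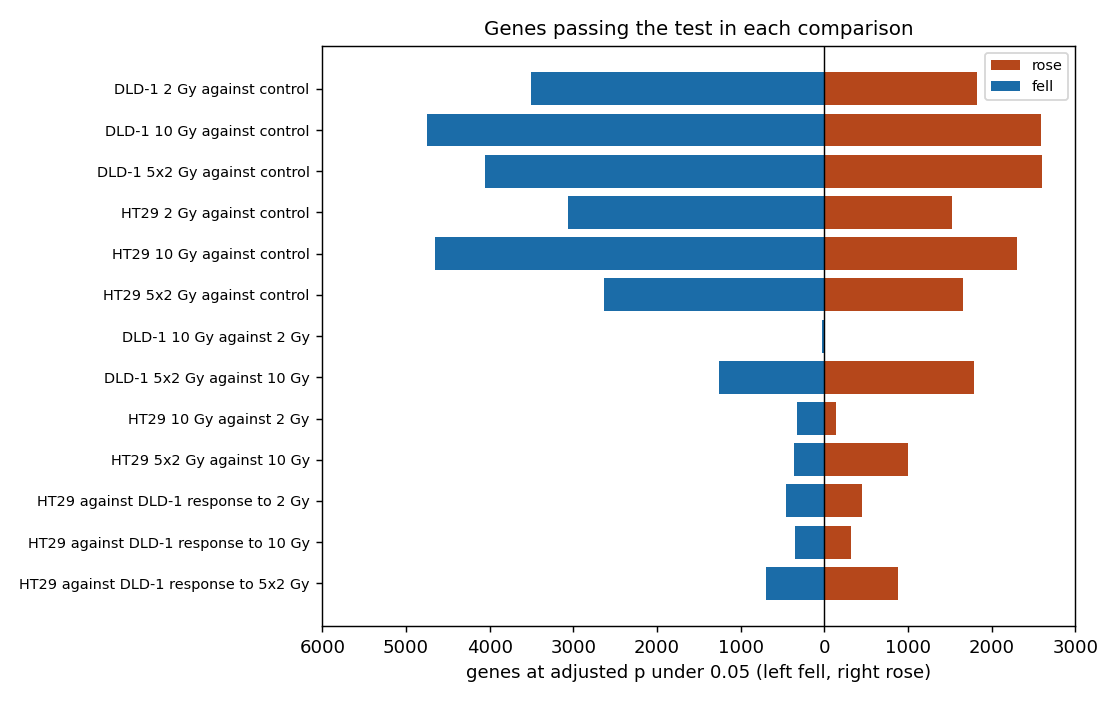
Number of genes passing at an adjusted p under 0.05 in each of the 13 comparisons (vertical axis), with genes that fell drawn to the left and genes that rose to the right (horizontal axis, number of genes). Comparisons against control passed 4294 to 7330 genes, and the comparison of 10 Gy with 2 Gy in DLD-1 passed 41.

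The comparison of 2 Gy with unirradiated DLD-1 cells asked what a low single dose changed at 4 h. The gene values below are ratios to control and can hold a constant dye difference. Of 5325 genes passing against control, 177 passed in the same direction against the mean of the 6 groups, and 3 in the opposite direction. The genes named below were not chosen by that test. RRM2, a subunit of ribonucleotide reductase, rose (0.50 ± 0.09, adjusted p = 2.5e-04). So did MCM10, a replication initiation factor (0.46 ± 0.09), and UNG, a uracil glycosylase (0.44 ± 0.10). Among mitotic regulators, PSRC1, a spindle protein, fell (-0.72 ± 0.09), and so did CDC25B, a CDK-activating phosphatase (-0.51 ± 0.08). Other lower mitotic genes were the kinase AURKA (-0.47 ± 0.09) and the kinase PLK1 (-0.47 ± 0.10, adjusted p = 0.0010). CCNB1, the mitotic cyclin B1, had -0.33 ± 0.10 (adjusted p = 0.018), which no longer passed when any 1 of the 3 arrays was left out or after median centring. JUNB, an AP-1 subunit, fell (-0.88 ± 0.13), and so did CCN1, a matricellular growth factor response gene (-0.41 ± 0.11, not passing without replicate 2). Lower genes further included HYOU1, an endoplasmic reticulum chaperone (-0.63 ± 0.07), and CDKN1A, the CDK inhibitor p21 (-0.36 ± 0.09, adjusted p = 0.0037). ANKRD12, which encodes an ankyrin repeat protein, rose (0.79 ± 0.08).

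Of 26 tested G1/S members, 8 rose, 1 fell and 17 did not pass (9 passed adjusted over the list alone), with a median of 0.11 (adjusted p = 0.011, and adjusted p = 0.63 with an estimated correlation). Double-strand break repair and checkpoint genes had 38 tested members, of which 9 rose, 2 fell and 27 did not pass (11 passed adjusted over the list alone). They lay higher as a list (adjusted p = 0.0499, and adjusted p = 0.57 with an estimated correlation). Histone genes fell as a list, and 0 rose, 8 fell and 8 did not pass (8 passed adjusted over the list alone) (adjusted p = 0.0499, and adjusted p = 0.92 with an estimated correlation). Of 40 listed ribosomal protein genes 10 were tested, of which 3 rose, 0 fell and 7 did not pass (3 passed adjusted over the list alone). The list test rested on only 5 of them (adjusted p = 0.016, and adjusted p = 0.48 with an estimated correlation). The G2/M and mitosis list did not pass, as 5 rose, 11 fell and 21 did not pass (16 passed adjusted over the list alone) (adjusted p = 0.76, and adjusted p = 0.92 with an estimated correlation). Against the mean of the 6 groups this list lay higher (median 0.09, adjusted p = 0.022, and adjusted p = 0.55 with an estimated correlation). On that measure 7 lists passed that had not passed against control, and with an estimated correlation only NF-kB and cytokine, which lay lower, did so (median -0.18, adjusted p = 4.4e-07, and adjusted p = 0.047 with an estimated correlation). The NF-kB medians against control on the 3 arrays were -0.05, 0.01 and 0.06. The mean of the 6 groups holds higher values of this list, such as 0.24 to 0.41 on the DLD-1 10 Gy arrays. Interferon-stimulated genes lay lower too (adjusted p = 7.3e-12, and adjusted p = 0.31 with an estimated correlation). Against control, however, their medians on the 3 arrays were -0.03, 0.09 and -0.01, and the mean of the 6 groups holds the high HT29 5x2 Gy values. Against that mean the repair list lay lower, opposite to its call against control (median -0.06, adjusted p = 0.022, and adjusted p = 0.31 with an estimated correlation). The G1/S (adjusted p = 0.10), histone (adjusted p = 0.39) and ribosomal protein lists (adjusted p = 0.21) did not pass against that mean. With the replicate number as a fixed block the calls of the ribosomal protein (adjusted p = 0.31), histone (adjusted p = 0.056) and repair lists (adjusted p = 0.056) against control were lost. Over all genes, 1821 rose and 3504 fell of 15784 tested, and 234 genes passed against the mean of the 6 groups. Without replicate 2 the count against control was 3266, the lowest of the 3 fits that left out an array.

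Next, DLD-1 cells after 1 dose of 10 Gy were compared with unirradiated cells. PSRC1 (-1.42 ± 0.09), AURKA (-1.36 ± 0.09), PLK1 (-1.34 ± 0.10, adjusted p = 2.9e-09) and CCNB1 (-1.01 ± 0.10) fell. CD83, an activation marker regulated by NF-kB, rose (1.04 ± 0.11). So did the chemokine CXCL3 (0.93 ± 0.11), the inhibitor NFKBIA (0.88 ± 0.08, adjusted p = 4.0e-08) and the NF-kB subunit RELB (0.86 ± 0.12). GDF15, a stress cytokine, rose (0.54 ± 0.11 from 2 arrays). CDKN1A had 0.23 ± 0.09 (adjusted p = 0.035), which no longer passed after median centring or scale normalization or without replicate 2 or 3. MDM2, a ubiquitin ligase, had 0.07 ± 0.07 (adjusted p = 0.44). PMAIP1, a BH3-only apoptosis gene, rose (0.58 ± 0.09), and CCND1, cyclin D1, fell (-0.51 ± 0.07).

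Of 38 tested G2/M and mitosis members, 1 rose, 29 fell and 8 did not pass (31 passed adjusted over the list alone), with a median of -0.51 (adjusted p = 3.1e-07, and adjusted p = 0.15 with an estimated correlation). Their median against the mean of the 6 groups was -0.32 (adjusted p = 1.2e-19, and adjusted p = 0.017 with an estimated correlation). In the NF-kB and cytokine list, 9 rose, 0 fell and 10 did not pass (10 passed adjusted over the list alone) (adjusted p = 1.3e-04, and adjusted p = 0.15 with an estimated correlation). The G1/S list, with MCM10 (0.67 ± 0.09) and the transcription factor E2F1 (0.60 ± 0.08) among its rises, had 29 tested members, of which 12 rose, 1 fell and 16 did not pass (13 passed adjusted over the list alone). It lay higher as a list (adjusted p = 1.3e-04, and adjusted p = 0.33 with an estimated correlation). Of 36 repair and checkpoint genes, 9 rose, 6 fell and 21 did not pass (15 passed adjusted over the list alone) (adjusted p = 0.051, not passing as a list). Against the mean of the 6 groups the NF-kB list passed in the same direction, but not with an estimated correlation (adjusted p = 0.011, and adjusted p = 0.49 with an estimated correlation), and the G1/S list did not pass (adjusted p = 0.49). Another 2 lists passed only against that mean, 1 higher and 1 lower, and 0 of them with an estimated correlation. In total 2584 genes rose and 4746 fell of 15647, and 1627 passed against the mean of the 6 groups.

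In DLD-1 after 5x2 Gy, ratios of proliferation transcripts to control were higher and those of sterol synthesis transcripts lower. TOP2A, topoisomerase II alpha (0.94 ± 0.06, adjusted p = 1.0e-09), the mitotic kinase CDK1 (0.81 ± 0.07) and the ubiquitin-conjugating enzyme UBE2C (0.76 ± 0.09) rose. The checkpoint kinase BUB1B (0.74 ± 0.08), PLK1 (0.51 ± 0.10) and CCNB1 (0.50 ± 0.10) rose too. In DNA synthesis, RRM2 (0.96 ± 0.09), MCM10 (0.84 ± 0.09) and the helicase subunit MCM2 (0.77 ± 0.10) rose. Recombination genes with higher ratios were the nuclease EXO1 (0.75 ± 0.07) and RAD54L (0.67 ± 0.09). MSMO1 (-1.13 ± 0.10), MVK (-0.78 ± 0.08) and IDI1 (-0.74 ± 0.09), which encode enzymes of sterol synthesis, fell. The aldolase gene ALDOC (-1.50 ± 0.13, adjusted p = 5.9e-08), the hypoxia-induced ANGPTL4 (-1.19 ± 0.08) and the glycolysis regulator PFKFB4 (-1.05 ± 0.10) also fell. CDKN1A rose (0.61 ± 0.09, adjusted p = 1.8e-05), and the BH3-only gene BBC3 fell (-0.84 ± 0.08). CCN1 (0.97 ± 0.11), the semaphorin coreceptor NRP1 (1.04 ± 0.08) and the DNA sensor CGAS (1.02 ± 0.08) rose.

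For the G2/M and mitosis list, 36 members were tested and 27 rose, 1 fell and 8 did not pass (29 passed adjusted over the list alone), with a median of 0.45. As a list they lay higher (adjusted p = 1.5e-13, and adjusted p = 0.023 with an estimated correlation). G1/S genes gave a median of 0.49, and of 29 tested, 22 rose, 0 fell and 7 did not pass (23 passed adjusted over the list alone) (adjusted p = 1.5e-13, and adjusted p = 0.023 with an estimated correlation). Repair and checkpoint genes numbered 38, of which 26 rose, 2 fell and 10 did not pass (29 passed adjusted over the list alone) (adjusted p = 5.8e-11, and adjusted p = 0.0072 with an estimated correlation). Cholesterol synthesis had a median of -0.51, and of 22 members, 0 rose, 18 fell and 4 did not pass (18 passed adjusted over the list alone). Its test gave adjusted p = 4.3e-08, and adjusted p = 0.029 with an estimated correlation. In hypoxia and glycolysis, 1 rose, 15 fell and 10 did not pass (16 passed adjusted over the list alone) (adjusted p = 0.0050, and adjusted p = 0.24 with an estimated correlation). Heat shock genes lay higher, and 8 rose, 0 fell and 4 did not pass (8 passed adjusted over the list alone) (adjusted p = 0.0047, and adjusted p = 0.029 with an estimated correlation, on 9 members). In the NF-kB and cytokine list, 7 rose, 1 fell and 11 did not pass (8 passed adjusted over the list alone) (adjusted p = 0.024, and adjusted p = 0.24 with an estimated correlation). Immediate early genes also lay higher, and 10 rose, 4 fell and 11 did not pass (15 passed adjusted over the list alone) (adjusted p = 0.038, and adjusted p = 0.33 with an estimated correlation). Of 15774 genes, 2603 rose and 4059 fell, a split that became 4141 and 2816 under median centring. Against the mean of the 6 groups 2939 genes passed. The G2/M, G1/S, repair, cholesterol and hypoxia lists passed there in the same direction, although with an estimated correlation the G1/S (adjusted p = 0.058) and hypoxia calls (adjusted p = 0.058) were lost. Stem cell and Wnt genes, not passing against control, lay higher there (median 0.19, adjusted p = 0.0026, and adjusted p = 0.021 with an estimated correlation). There the heat shock (adjusted p = 0.32), NF-kB (adjusted p = 0.80) and immediate early lists (adjusted p = 0.066) did not pass at all.

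In HT29 cells after 2 Gy, some mitotic and differentiation transcripts had lower ratios to control. These ratios can also hold a constant dye difference. Of 4591 genes passing against control, 561 passed in the same direction against the mean of the 6 groups, and 33 in the opposite direction. The genes named below were not chosen by that test. CENPE, a kinetochore motor (-0.68 ± 0.07, adjusted p = 6.1e-07), the spindle pole protein ASPM (-0.61 ± 0.09) and the kinesin KIF2C (-0.54 ± 0.10) fell. PLK1 fell at its brightest probe (-0.43 ± 0.10), while its other probe had the opposite sign, and neither the mean of both nor the value after median centring passed. CCNB1 had -0.26 ± 0.10 (adjusted p = 0.062), and 0.079 after median centring. MUC5AC, a secreted mucin (-0.79 ± 0.10), and the intestinal transcription factor CDX1 (-0.57 ± 0.07) fell. So did GCLM, a glutathione synthesis subunit (-0.56 ± 0.11), and the death receptor TNFRSF10B (-0.50 ± 0.09), which did not pass with median spot signals. CHEK2, a checkpoint kinase (0.66 ± 0.10), MCM10 (0.53 ± 0.09) and CLSPN, a replication checkpoint adaptor (0.50 ± 0.08), rose. CDKN1A had -0.05 ± 0.09 (adjusted p = 0.70).

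No gene list passed as a whole against control in HT29 after 2 Gy. In G2/M and mitosis, 3 rose, 15 fell and 19 did not pass (20 passed adjusted over the list alone) (adjusted p = 0.093, and adjusted p = 0.77 with an estimated correlation), and in differentiation, 0 rose, 6 fell and 18 did not pass (5 passed adjusted over the list alone) (adjusted p = 0.53). The median of the differentiation list was negative on every array of both lines, so it was not particular to this group. Of 38 repair and checkpoint genes, 8 rose, 5 fell and 25 did not pass (16 passed adjusted over the list alone) (adjusted p = 0.093). With the group set against the mean of the 6 groups 7 lists passed, 2 higher and 5 lower, the latter including repair (median -0.09, adjusted p = 0.0040) and G1/S (median -0.16, adjusted p = 1.6e-05). With an estimated correlation 0 of these 7 passed (adjusted p = 0.22 for G1/S and repair). Single genes that passed numbered 1522 higher and 3069 lower of 15745, and 1203 passed against the mean of the 6 groups. Leaving out HT29 2 Gy replicate 1 gave 2730 genes and leaving out replicate 3 gave 2799.

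For the single dose of 10 Gy, HT29 cells were likewise compared with unirradiated cells. PLK1 (-1.45 ± 0.10, adjusted p = 1.0e-09), CENPE (-1.41 ± 0.07), PSRC1 (-1.34 ± 0.09), the kinesin KIF23 (-1.20 ± 0.10) and CCNB1 (-1.12 ± 0.10) fell. Among NF-kB targets, NFKBIE (0.83 ± 0.08), the apoptosis inhibitor BIRC3 (0.72 ± 0.08) and NFKBIA (0.66 ± 0.08, adjusted p = 2.1e-06) rose. CD83 (0.79 ± 0.11) and PTGS2, cyclooxygenase-2 (0.77 ± 0.07), rose as well. Replication genes with higher ratios were UNG (0.59 ± 0.10), CLSPN (0.54 ± 0.08) and E2F1 (0.47 ± 0.08). The HSP90 cochaperone CHORDC1 (0.76 ± 0.11) and HSP90AA1 (0.61 ± 0.13) rose, and ATOH1, the secretory lineage transcription factor, fell (-0.74 ± 0.11). CDKN1A had -0.16 ± 0.09 (adjusted p = 0.15) and MDM2 0.09 ± 0.07 (adjusted p = 0.33).

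Of 38 tested G2/M and mitosis genes, 0 rose, 32 fell and 6 did not pass (33 passed adjusted over the list alone), with a median of -0.64 (adjusted p = 2.6e-14, and adjusted p = 0.045 with an estimated correlation). In the G1/S list, 11 rose, 2 fell and 14 did not pass (13 passed adjusted over the list alone) (adjusted p = 4.1e-04, and adjusted p = 0.35 with an estimated correlation). Repair and checkpoint genes lay higher, and 11 rose, 7 fell and 19 did not pass (18 passed adjusted over the list alone) (adjusted p = 0.016, and adjusted p = 0.34 with an estimated correlation). NF-kB and cytokine genes lay higher, and 6 rose, 0 fell and 13 did not pass (6 passed adjusted over the list alone) (adjusted p = 4.4e-04, and adjusted p = 0.11 with an estimated correlation). Heat shock genes lay higher as well, and 7 rose, 1 fell and 6 did not pass (9 passed adjusted over the list alone) (adjusted p = 0.0060, and adjusted p = 0.074 with an estimated correlation). Histone genes fell, and 0 rose, 11 fell and 6 did not pass (11 passed adjusted over the list alone) (adjusted p = 0.014, and adjusted p = 0.54 with an estimated correlation). The G2/M list passed in the same direction against the mean of the 6 groups (median -0.48, adjusted p = 3.2e-38, and adjusted p = 9.0e-04 with an estimated correlation). The G1/S (adjusted p = 0.43), repair (adjusted p = 0.36), NF-kB (adjusted p = 0.069), heat shock (adjusted p = 0.13) and histone lists (adjusted p = 0.057) did not pass there. Another 2 lists passed only there, 1 higher and 1 lower, and 0 of them with an estimated correlation. In all, 2303 genes rose and 4655 fell of 15768, and 958 passed against the mean of the 6 groups. Without replicate 2 the count against control was 4427.

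Interferon-stimulated genes were higher in HT29 after 5x2 Gy. IFI44L (2.28 ± 0.18, adjusted p = 1.6e-08), the antiviral GTPase MX1 (1.98 ± 0.19), OASL (1.78 ± 0.10) and IFI44 (1.75 ± 0.14) were higher on all 3 arrays. The chemokines CXCL10 (0.94 ± 0.10) and CXCL11 (0.91 ± 0.07) rose. In antigen presentation, higher genes were the peptide transporter subunits TAP1 (1.21 ± 0.15) and TAP2 (0.81 ± 0.09) and the immunoproteasome subunit PSMB9 (1.06 ± 0.14). DHRS2, a dehydrogenase gene (1.48 ± 0.10), BIRC3 (0.65 ± 0.08) and PMAIP1 (0.77 ± 0.09) rose. Repair and checkpoint genes with higher ratios were the DNA damage mediator MDC1 (0.63 ± 0.13), CHEK2 (0.48 ± 0.10) and RAD54L (0.41 ± 0.09). The sterol synthesis genes MVD (-0.43 ± 0.09), MSMO1 (-0.41 ± 0.10) and HMGCS1 (-0.38 ± 0.09) fell. MSMO1 and HMGCS1 did not pass after median centring or without replicate 1, nor MVD without replicate 2. CDKN1A had -0.13 ± 0.09 (adjusted p = 0.29).

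Of 38 tested type I interferon-stimulated genes, 37 rose, 0 fell and 1 did not pass (37 passed adjusted over the list alone), with a median of 1.23 (adjusted p = 5.1e-50, and adjusted p = 0.022 with an estimated correlation). The medians of this list on the 3 arrays were 1.52, 0.81 and 1.28. MHC class I presentation genes lay higher, and 10 rose, 1 fell and 3 did not pass (12 passed adjusted over the list alone) (adjusted p = 5.0e-06, and adjusted p = 0.11 with an estimated correlation). Among repair and checkpoint genes, 18 rose, 0 fell and 18 did not pass (20 passed adjusted over the list alone) (adjusted p = 2.5e-06, and adjusted p = 0.022 with an estimated correlation). NF-kB and cytokine genes rose here too, and 11 rose, 0 fell and 8 did not pass (13 passed adjusted over the list alone) (adjusted p = 1.1e-06, and adjusted p = 0.022 with an estimated correlation). In the G1/S list, 6 rose, 1 fell and 23 did not pass (6 passed adjusted over the list alone) (adjusted p = 0.0034, and adjusted p = 0.39 with an estimated correlation). In the heat shock list, 4 rose, 0 fell and 9 did not pass (4 passed adjusted over the list alone) (adjusted p = 0.014, and adjusted p = 0.065 with an estimated correlation). Cholesterol synthesis fell as a list, and 0 rose, 8 fell and 12 did not pass (10 passed adjusted over the list alone) (adjusted p = 0.0044, and adjusted p = 0.28 with an estimated correlation). This call was lost after median centring (adjusted p = 0.29). In the G2/M list, which did not pass, 10 rose, 6 fell and 22 did not pass (17 passed adjusted over the list alone) (adjusted p = 0.82, and adjusted p = 0.97 with an estimated correlation). TOP2A had 0.35 ± 0.06 and CENPE -0.41 ± 0.07, while CCNB1 had -0.02 ± 0.10 (adjusted p = 0.93) and 0.23 after median centring. PLK1 had -0.42 ± 0.10 at its brightest probe and an opposite sign at its other probe, and did not pass after median centring. Over all genes, 1659 rose and 2635 fell of 15666, a split of 2623 and 1919 under median centring. Against the mean of the 6 groups 1000 genes passed, and the interferon, MHC and NF-kB lists passed in the same direction. With an estimated correlation only the interferon list kept that call (adjusted p = 0.0087, against 0.18 for MHC and 0.34 for NF-kB). The G1/S list lay lower there, opposite to its call against control (median -0.07, adjusted p = 0.018, and adjusted p = 0.47 with an estimated correlation), and the G2/M list higher (median 0.17, adjusted p = 1.1e-06, and adjusted p = 0.20 with an estimated correlation). The repair (adjusted p = 0.50), heat shock (adjusted p = 0.98) and cholesterol lists (adjusted p = 0.055) did not pass against that mean. Without replicate 2 or 3 the count against control was 2642 or 2612.

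**Figure D2:**
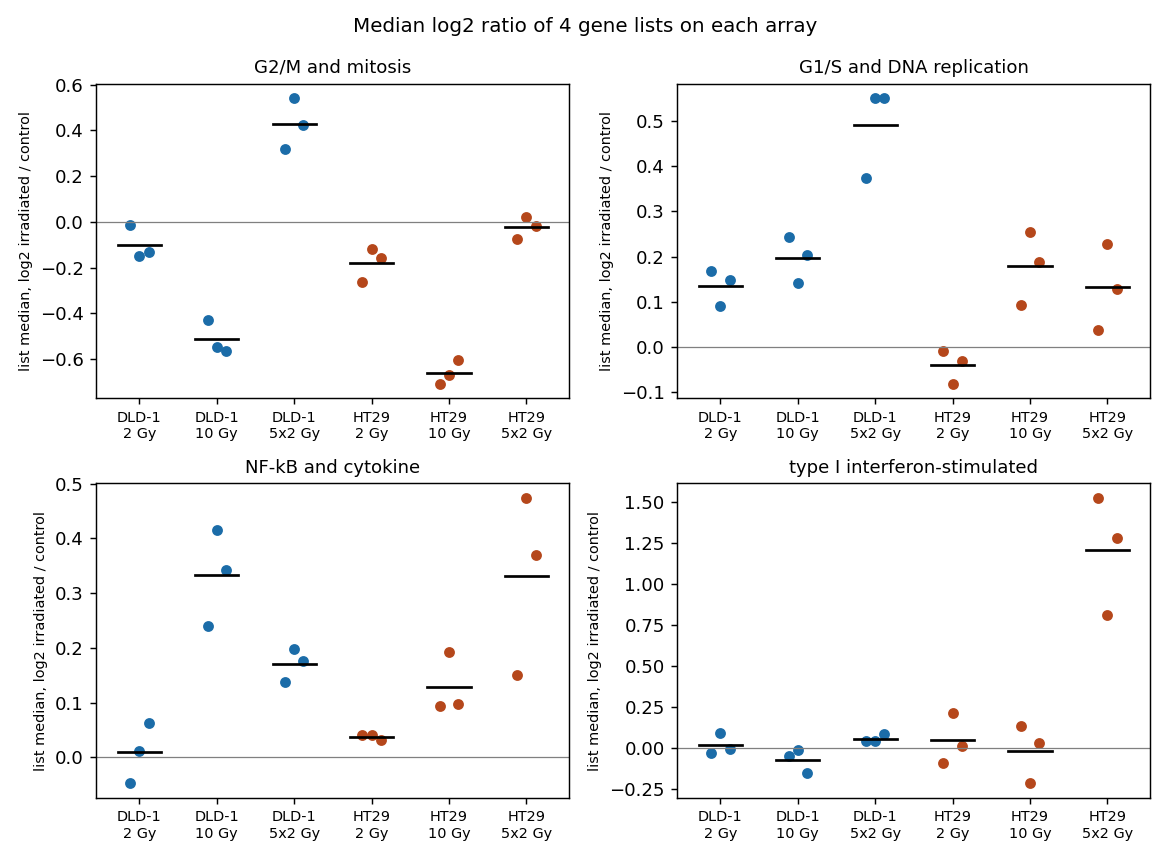
Median log2 ratio of irradiated over control RNA (vertical axis) on each array for 4 gene lists, by group (horizontal axis), with arrays as points and the mean of the 3 arrays as a line. The G2/M and mitosis medians lay between -0.71 and -0.43 on the 10 Gy arrays, and the interferon medians at 0.81 or above only on the HT29 5x2 Gy arrays.

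The direct comparison of 10 Gy with 2 Gy, in which constant dye differences cancel, asked what the higher dose changed. In DLD-1, PIF1, a helicase expressed in mitosis (-0.99 ± 0.16), AURKA (-0.89 ± 0.13) and PLK1 (-0.87 ± 0.14, adjusted p = 0.0092) were lower after 10 Gy. BORA, an activator of AURKA (-0.75 ± 0.12), the phosphatase CDC25C (-0.73 ± 0.12) and PSRC1 (-0.70 ± 0.12) were lower too. The NF-kB coregulator BCL3 (0.98 ± 0.11, adjusted p = 2.3e-04), the chemokines CCL20 (0.94 ± 0.15) and CXCL3 (0.90 ± 0.16), and NFKBIA (0.67 ± 0.11) were higher. CD83 (0.75 ± 0.15) and CDKN1A (0.59 ± 0.12, adjusted p = 0.047) were higher too, but neither passed after median centring, and CDKN1A lost its call when any 1 array was left out. Of 35 tested G2/M and mitosis genes, 0 rose, 8 fell and 27 did not pass (24 passed adjusted over the list alone), with a median of -0.41 (adjusted p = 9.5e-24, and adjusted p = 0.0062 with an estimated correlation). Only replicate 3 of DLD-1 2 Gy shared a slide with the 10 Gy arrays, so values with the slide as a fixed block or within that slide rest on 1 array of 2 Gy. The list median was then -0.40 and -0.39. From all arrays it was -0.42 in the Cy5 channel alone and 0.03 in the control channel, and it lay 0.488 below the median of the G1/S list. Of NF-kB and cytokine genes, 3 rose, 0 fell and 16 did not pass (6 passed adjusted over the list alone) (adjusted p = 6.8e-10, and adjusted p = 0.0062 with an estimated correlation). For immediate early genes, 0 rose, 0 fell and 26 did not pass (0 passed adjusted over the list alone). That list lay higher (adjusted p = 0.015, and adjusted p = 0.38 with an estimated correlation), a call lost after median centring (adjusted p = 0.086) and with the slide as a fixed block (adjusted p = 0.052). Of 15395 genes, 11 rose and 30 fell, and 8 rose and 9 fell after scale normalization. The total of 41 was 2 without DLD-1 2 Gy replicate 1, 26 without 2 Gy replicate 2, and 4 and 17 without 10 Gy replicates 3 and 1. With its 1 array of 2 Gy, the fit with the slide as a fixed block passed 0 genes in limma (881 at an unadjusted p under 0.05), and the fit within that slide passed 0 (931 at an unadjusted p under 0.05). These are not tests of 3 against 3 arrays.

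In HT29, PIF1 (-1.07 ± 0.16), PLK1 (-1.02 ± 0.14, adjusted p = 8.6e-04), the kinesin KIF20A (-0.96 ± 0.11), PSRC1 (-0.91 ± 0.12) and CCNB1 (-0.86 ± 0.15) were lower after 10 Gy. BIRC3 (0.76 ± 0.12), NFKBIA (0.63 ± 0.11, adjusted p = 0.0070) and NFKBIE (0.61 ± 0.12) were higher. Other higher genes were the kinase RIPK1 (0.71 ± 0.14), PTGS2 (0.67 ± 0.11) and TNFRSF10B (0.60 ± 0.13). The histone gene H4C2 (-0.87 ± 0.16) and ATOH1 (-0.83 ± 0.16) were lower. Of 35 G2/M and mitosis genes, 0 rose, 17 fell and 18 did not pass (29 passed adjusted over the list alone), with a median of -0.48 (adjusted p = 3.4e-23, and adjusted p = 0.0075 with an estimated correlation). Only replicate 1 of HT29 2 Gy lay on the slide of the 10 Gy arrays, and from this 1 array of 2 Gy the median was -0.35 with the slide as a fixed block and -0.38 within that slide. From all arrays the Cy5 channel alone gave -0.44, the control channel 0.05, and the list lay 0.633 below the median of the G1/S list. In the NF-kB and cytokine list, higher after 10 Gy, 4 rose, 0 fell and 15 did not pass (6 passed adjusted over the list alone) (adjusted p = 6.7e-06, and adjusted p = 0.045 with an estimated correlation).

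Between 10 Gy and 2 Gy in HT29, G1/S genes lay higher, and 2 rose, 0 fell and 24 did not pass (7 passed adjusted over the list alone) (adjusted p = 2.2e-05, and adjusted p = 0.23 with an estimated correlation). Immediate early genes lay higher, and 1 rose, 0 fell and 26 did not pass (1 passed adjusted over the list alone) (adjusted p = 0.031, and adjusted p = 0.40 with an estimated correlation). Histone genes lay lower, and 0 rose, 1 fell and 15 did not pass (6 passed adjusted over the list alone) (adjusted p = 2.2e-05, and adjusted p = 0.23 with an estimated correlation). Oxidative phosphorylation genes lay lower, and 0 rose, 2 fell and 15 did not pass (5 passed adjusted over the list alone) (adjusted p = 0.031, and adjusted p = 0.13 with an estimated correlation). Metallothioneins, which bind metals, lay lower, and 0 rose, 0 fell and 5 did not pass (3 passed adjusted over the list alone) (adjusted p = 0.029, and adjusted p = 0.28 with an estimated correlation), a call lost with the slide as a fixed block and so 1 array of 2 Gy (adjusted p = 0.079). Of 15462 genes, 133 rose and 330 fell. The total of 463 was 25 without HT29 10 Gy replicate 2, 46 without replicate 3 and 1215 without replicate 1. It was 101 and 127 without HT29 2 Gy replicates 1 and 3, 8 when fitted on its own 6 arrays, and 92 with the slide as a fixed block, which leaves 1 array of 2 Gy.

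**Figure D3:**
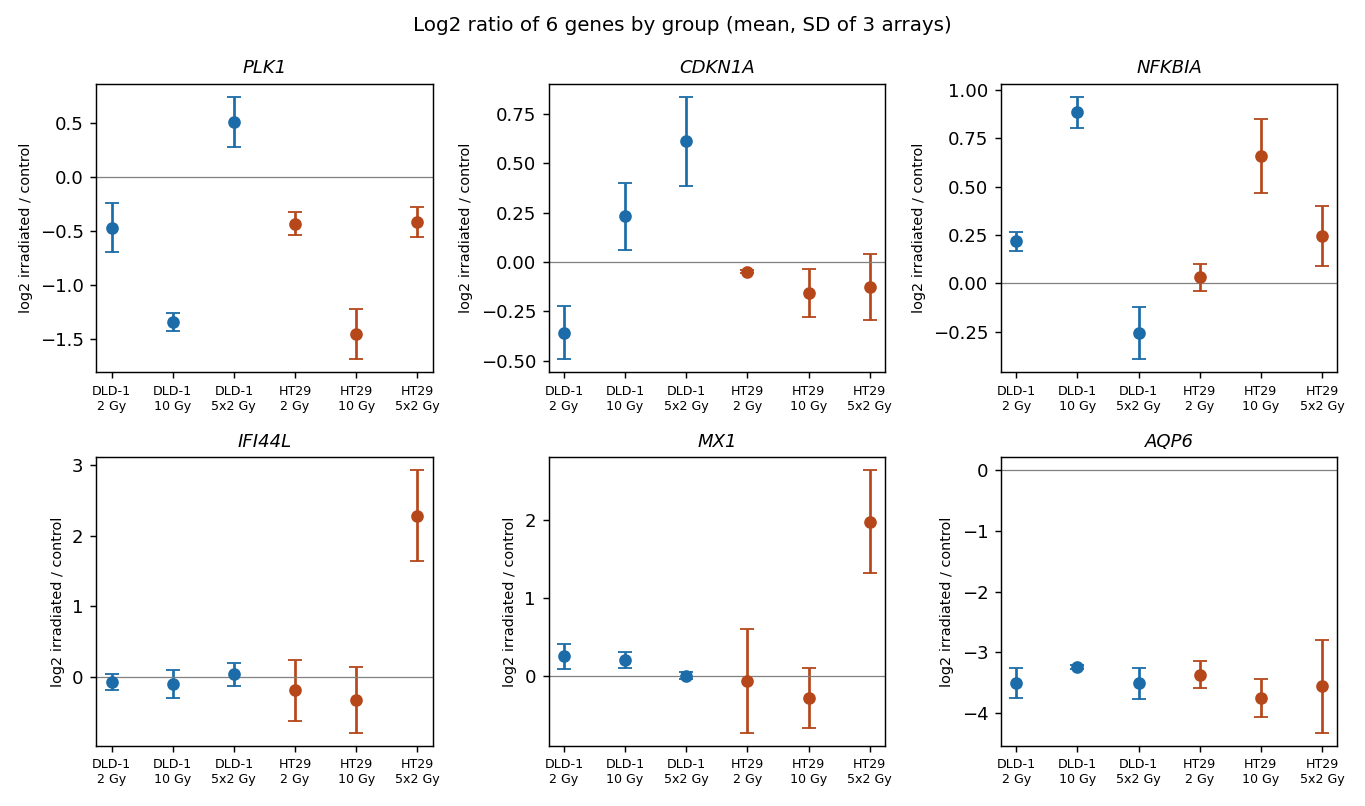
Log2 ratio of irradiated over control RNA (vertical axis) for 6 genes in the 6 groups (horizontal axis), as the mean and SD of 3 arrays. PLK1 was lowest after 10 Gy in both lines, IFI44L and MX1 were highest after 5x2 Gy in HT29, and AQP6 lay between -3.74 and -3.24 in every group.

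Fractionation was compared with 1 dose of equal total by setting 5x2 Gy against 10 Gy, with values as differences between ratios to control. In DLD-1, PLK1 (1.85 ± 0.14, adjusted p = 2.3e-07), AURKA (1.56 ± 0.13) and CCNB1 (1.51 ± 0.15) were higher after 5x2 Gy. CCN1 (1.31 ± 0.15), the interferon-induced OAS3 (0.88 ± 0.13), the Fanconi anaemia genes FANCD2 (0.80 ± 0.15) and FANCI (0.62 ± 0.11), and the small nucleolar RNA SNORD3B-1 (2.26 ± 0.28) were higher too. NFKBIA (-1.14 ± 0.11) and BCL3 (-1.12 ± 0.11) were lower. So were the sterol synthesis genes MSMO1 (-0.93 ± 0.14) and SQLE (-0.75 ± 0.12). Lower genes further included the collagen hydroxylase P4HA1 (-1.25 ± 0.19), ANGPTL4 (-1.17 ± 0.12), ALDOC (-1.12 ± 0.18) and the noncoding RNA MALAT1 (-2.81 ± 0.69). The Cy3 channel also differed, in 6173 of 15377 genes, between the 5x2 Gy and the 10 Gy arrays, which shared no slide, against 0 between 10 Gy and 2 Gy arrays of either line. For 57.4% of the called genes the control channel moved more than the irradiated channel and against the ratio. In Cy5 alone ALDOC (1.94), ANGPTL4 (1.33), P4HA1 (0.78) and MSMO1 (0.53) had the sign opposite to their ratios. So had MALAT1 (0.084), FANCI (-0.070) and CCN1 (-0.41).

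Of 35 G2/M and mitosis genes in DLD-1, 34 rose, 0 fell and 1 did not pass (35 passed adjusted over the list alone). Their median was 0.93 (adjusted p = 3.2e-35, and adjusted p = 7.7e-04 with an estimated correlation), with channel medians of 0.30 in Cy5 and -0.64 in Cy3. For G1/S genes, 9 rose, 1 fell and 17 did not pass (14 passed adjusted over the list alone) (adjusted p = 8.6e-04, and adjusted p = 0.32 with an estimated correlation), with channel medians of -0.65 in Cy5 and -1.07 in Cy3. Of repair and checkpoint genes, 12 rose, 0 fell and 24 did not pass (14 passed adjusted over the list alone) (adjusted p = 7.0e-05, and adjusted p = 0.055 with an estimated correlation). The repair list had channel medians of -0.29 in Cy5 and -0.59 in Cy3, both negative, and a shift common to both channels cannot be separated here. Of stem cell and Wnt genes, 9 rose, 1 fell and 8 did not pass (10 passed adjusted over the list alone) (adjusted p = 0.014, and adjusted p = 0.055 with an estimated correlation). Hypoxia and glycolysis genes lay lower in the ratio, and 1 rose, 11 fell and 14 did not pass (13 passed adjusted over the list alone) (adjusted p = 1.6e-05, and adjusted p = 0.075 with an estimated correlation). Their channel medians were 0.51 in Cy5 and 0.82 in Cy3. Cholesterol synthesis genes lay lower, and 0 rose, 11 fell and 9 did not pass (14 passed adjusted over the list alone) (adjusted p = 7.8e-10, and adjusted p = 0.030 with an estimated correlation), with channel medians of -0.10 in Cy5 and 0.34 in Cy3. Of 15377 genes, 1785 rose and 1256 fell, and under median centring 3066 rose and 786 fell. No slide held both groups, and a fixed slide block could not be fitted. Without DLD-1 10 Gy replicate 1 the count was 1963, and without DLD-1 5x2 Gy replicate 3 it was 2022.

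In HT29, the ratios of interferon and mitotic transcripts to control were higher after 5x2 Gy than after 10 Gy. MX1 (2.26 ± 0.28, adjusted p = 3.8e-05), OAS2 (2.05 ± 0.18), the chemokine CCL5 (1.58 ± 0.12) and DHRS2 (1.81 ± 0.14) were higher. The kinesins KIF18A (1.24 ± 0.12) and KIF23 (1.22 ± 0.15), CCNB1 (1.10 ± 0.15) and PLK1 (1.04 ± 0.14) were higher too. So were PSMB9 (1.26 ± 0.20), TAP1 (1.01 ± 0.21) and the stress regulator NUPR1 (0.85 ± 0.14). PTGS2 (-0.78 ± 0.11) and MSMO1 (-0.54 ± 0.14) were lower. MSMO1 did not pass after median centring and had 0.48 in Cy5 alone. Of 38 interferon-stimulated genes, 36 rose, 0 fell and 2 did not pass (37 passed adjusted over the list alone), with a median of 1.21 (adjusted p = 1.9e-47, and adjusted p = 0.024 with an estimated correlation). Channel medians of this list were 1.45 in Cy5 and 0.11 in Cy3. Of 36 G2/M and mitosis genes, 29 rose, 0 fell and 7 did not pass (34 passed adjusted over the list alone), with a median of 0.61 (adjusted p = 5.8e-28, and adjusted p = 0.0036 with an estimated correlation). Here the channel medians were -0.11 in Cy5 and -0.71 in Cy3. Channels compared between arrays without a common slide can hold a shift of both, so these medians do not show which RNA changed. As ratios to control, the medians of this list on single arrays were -0.71 to -0.61 at 10 Gy and -0.08 to 0.02 at 5x2 Gy.

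MHC class I presentation genes in HT29 lay higher after 5x2 Gy than after 10 Gy, and 5 rose, 0 fell and 9 did not pass (8 passed adjusted over the list alone) (adjusted p = 3.9e-05, and adjusted p = 0.20 with an estimated correlation). The MHC list had channel medians of 0.18 in Cy5 and -0.17 in Cy3. Histone genes lay higher, and 2 rose, 0 fell and 14 did not pass (8 passed adjusted over the list alone) (adjusted p = 0.0018, and adjusted p = 0.45 with an estimated correlation). Matrix, integrin and protease genes lay higher, and 7 rose, 0 fell and 22 did not pass (11 passed adjusted over the list alone) (adjusted p = 0.0091, and adjusted p = 0.40 with an estimated correlation). Cholesterol synthesis genes lay lower, and 0 rose, 3 fell and 17 did not pass (5 passed adjusted over the list alone) (adjusted p = 1.3e-04, and adjusted p = 0.20 with an estimated correlation), with channel medians of 0.10 in Cy5 and 0.33 in Cy3. Of 15397 genes, 1005 rose and 360 fell. In the control channel 3734 differed, and for 35.9% of the called genes that channel moved more and against the ratio. The 5x2 Gy and 10 Gy arrays shared no slide, and a fixed slide block joined them through the 2 Gy arrays, with 1 of these on the slide of the 10 Gy arrays. The count was then 19, and MX1, OAS2, CCNB1 and PLK1 were among the genes that no longer passed. The interferon median with that block was 0.95 and the G2/M median 0.47. The MHC list (adjusted p = 0.24) and the matrix list (adjusted p = 0.24) did not pass. The count of 1365 was 517 and 653 without HT29 10 Gy replicates 2 and 3, 632 and 666 without HT29 5x2 Gy replicates 1 and 3, and 453 on its own 6 arrays.

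**Figure D4:**
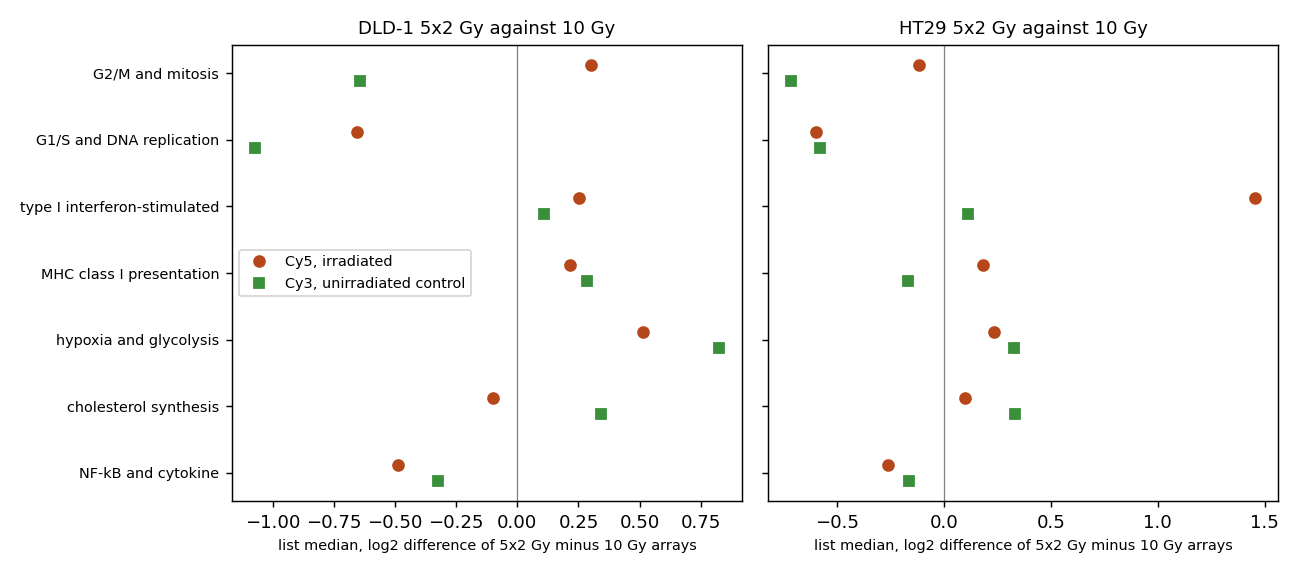
Median log2 difference between the 5x2 Gy and the 10 Gy arrays (horizontal axis) of 7 gene lists (vertical axis), in the Cy5 channel of irradiated RNA and the Cy3 channel of control RNA. In HT29 the interferon list had 1.45 in Cy5 and 0.11 in Cy3, while for G2/M and mitosis the Cy3 medians were -0.64 in DLD-1 and -0.71 in HT29.

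Whether the lines answered a treatment differently was tested as the HT29 minus the DLD-1 log2 ratio. At 2 Gy and at 10 Gy the lines shared no slide, so line and slide cannot be separated in these differences. At 2 Gy, PCGF1, a Polycomb ring finger gene (1.04 ± 0.17, adjusted p = 0.0024), the small GTPase RHOD (0.88 ± 0.12) and JUNB (0.84 ± 0.18) had the higher ratio in HT29. So had CHEK2 (0.60 ± 0.14) and HYOU1 (0.56 ± 0.11). The fucosyltransferase FUT4 (-0.84 ± 0.14), the phosphatase subunit PPP1R12C (-0.87 ± 0.10) and the checkpoint kinase BUB1 (-0.54 ± 0.10) had the lower ratio in HT29. CENPE (-0.39 ± 0.10), BARD1 (-0.42 ± 0.10) and its repair partner BRCA1 (-0.41 ± 0.10) were lower too, although none of these 3 passed without DLD-1 or HT29 2 Gy replicate 1, and CENPE did not pass after median centring. Histone ratios were higher in HT29 as a list, and 1 rose, 0 fell and 15 did not pass (4 passed adjusted over the list alone) (adjusted p = 0.0094, and adjusted p = 0.94 with an estimated correlation). Oxidative phosphorylation ratios were higher in HT29, and 2 rose, 0 fell and 16 did not pass (5 passed adjusted over the list alone) (adjusted p = 0.044, and adjusted p = 0.22 with an estimated correlation), a call lost with the replicate number as a fixed block (adjusted p = 0.092). Of the genes tested, 447 had a higher and 456 a lower ratio in HT29. The total of 903 was 211 without HT29 2 Gy replicate 1, 460 without HT29 2 Gy replicate 3, 376 to 486 without any 1 DLD-1 array, and 469 when fitted on the 6 arrays alone.

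At 10 Gy, BTG2 (-0.89 ± 0.13, adjusted p = 0.0019), the nuclear receptor NR0B2 (-1.11 ± 0.12), CXCL3 (-0.75 ± 0.16), CENPE (-0.58 ± 0.10) and KIF20A (-0.52 ± 0.11) had the lower ratio in HT29. TAP2 (-0.52 ± 0.12) was lower too but did not pass after median centring. CCND1 (0.50 ± 0.10) and the HSP70 cochaperone BAG3 (0.61 ± 0.11) had the higher ratio. The G2/M and mitosis list was lower in HT29, and 1 rose, 7 fell and 28 did not pass (10 passed adjusted over the list alone) (adjusted p = 0.0061, and adjusted p = 0.62 with an estimated correlation). That call was also lost after median centring (adjusted p = 0.13). Ratios were higher in HT29 for 312 genes and lower for 353, and for 295 and 207 after median centring. Leaving out 1 array gave 159 to 404 genes, the fewest without DLD-1 10 Gy replicate 3, and the 6 arrays alone gave 150.

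After 5x2 Gy the lines differed in interferon and cell cycle genes. IFI44L (2.24 ± 0.25, adjusted p = 1.4e-05), MX1 (1.97 ± 0.28), MX2 (1.85 ± 0.16) and the interferon signalling factor IRF9 (1.54 ± 0.16) had the higher ratio in HT29. So had TAP1 (1.30 ± 0.21), PSMB9 (1.24 ± 0.20) and CXCL10 (1.06 ± 0.15). ANGPTL4 (1.31 ± 0.12), MSMO1 (0.71 ± 0.14) and BBC3 (0.74 ± 0.12) were also higher in HT29. The cell cycle transcription factor MYBL2 (-1.04 ± 0.12), PLK1 (-0.92 ± 0.14), TOP2A (-0.60 ± 0.09), RRM2 (-0.68 ± 0.12) and the replication clamp PCNA (-0.50 ± 0.09) had the lower ratio in HT29. CDKN1A (-0.74 ± 0.12, adjusted p = 7.8e-04), the matrix protein THBS1 (-0.96 ± 0.12) and the transcription factor ETS1 (-1.11 ± 0.11) were lower too. Of 38 interferon-stimulated genes, 37 rose, 0 fell and 1 did not pass (37 passed adjusted over the list alone), with a median of 1.20 (adjusted p = 6.3e-49, and adjusted p = 0.021 with an estimated correlation). Only replicate 3 of HT29 5x2 Gy shared a slide with the DLD-1 5x2 Gy arrays, and within that slide, from 1 HT29 array, the median was 1.26. For G2/M and mitosis genes, 0 rose, 21 fell and 15 did not pass (28 passed adjusted over the list alone) (adjusted p = 4.6e-18, and adjusted p = 0.016 with an estimated correlation), with a median of -0.42 from that 1 array. For the G1/S list, 0 rose, 10 fell and 18 did not pass (21 passed adjusted over the list alone) (adjusted p = 1.2e-11, and adjusted p = 0.041 with an estimated correlation), with a median of -0.38 from that 1 array.

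Hypoxia and glycolysis ratios after 5x2 Gy were higher in HT29, and 10 rose, 2 fell and 13 did not pass (14 passed adjusted over the list alone) (adjusted p = 1.5e-04, and adjusted p = 0.10 with an estimated correlation). MHC class I presentation was higher in HT29, and 6 rose, 0 fell and 6 did not pass (7 passed adjusted over the list alone) (adjusted p = 1.5e-04, and adjusted p = 0.10 with an estimated correlation). Cholesterol synthesis was higher, and 5 rose, 0 fell and 15 did not pass (6 passed adjusted over the list alone) (adjusted p = 4.7e-05, and adjusted p = 0.079 with an estimated correlation). Histones were higher, and 4 rose, 1 fell and 10 did not pass (7 passed adjusted over the list alone) (adjusted p = 0.0096, and adjusted p = 0.32 with an estimated correlation). Apoptosis regulators, which hold promoters and inhibitors of cell death, were higher, and 5 rose, 0 fell and 21 did not pass (7 passed adjusted over the list alone) (adjusted p = 0.041, and adjusted p = 0.079 with an estimated correlation). Repair and checkpoint genes were lower, and 0 rose, 7 fell and 29 did not pass (8 passed adjusted over the list alone) (adjusted p = 8.1e-04, and adjusted p = 0.079 with an estimated correlation). Stem cell and Wnt genes were lower, and 1 rose, 3 fell and 14 did not pass (7 passed adjusted over the list alone) (adjusted p = 0.015, and adjusted p = 0.067 with an estimated correlation). Immediate early genes were lower, and 2 rose, 4 fell and 19 did not pass (8 passed adjusted over the list alone) (adjusted p = 0.037, and adjusted p = 0.32 with an estimated correlation). With the slide as a fixed block, which rests on 1 HT29 array, the immediate early (adjusted p = 0.14) and apoptosis lists (adjusted p = 0.14) did not pass, and the apoptosis list did not pass after median centring (adjusted p = 0.12). Of all genes, 882 had a higher and 695 a lower ratio in HT29, and 492 and 722 under median centring. The total of 1577 was 795 and 1041 without HT29 5x2 Gy replicates 1 and 3, and 839 and 935 without DLD-1 5x2 Gy replicates 3 and 2. It was 207 with the slide as a fixed block and 216 within the shared slide, both from 1 HT29 array.

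Whether both lines had genes called in the same direction was counted directly. Between 10 Gy and 2 Gy, 3 genes rose and 16 fell in both lines, where 0.0898 and 0.631 would overlap between independent lists, and 0 moved in opposite directions. Between 5x2 Gy and 10 Gy, 271 rose and 99 fell in both lines (111.8 and 28.7 between independent lists) and 54 went opposite ways. Within a line, called genes with the same direction against control numbered 4088 for 2 and 10 Gy in DLD-1 (r = 0.835 across genes, covariance 0.0742) and 3032 in HT29 (r = 0.723, covariance 0.0575). If those comparisons shared their control RNA, unchanged groups would give r of 0.491 and 0.500 and covariances of 0.00415 and 0.00428. The 4 pairs with 5x2 Gy had r of 0.568 to 0.621, against 0.495 to 0.512 for unchanged groups with shared control RNA. Their covariances were 0.0378 to 0.0574 against 0.00414 to 0.00431. These 4 pairs had 1922 to 3350 genes in the same direction. The unchanged groups were simulated without dye differences, so an r near theirs does not tell whether control RNA was shared. Genes called in opposite directions numbered 224 for 2 and 5x2 Gy and 386 for 10 and 5x2 Gy in DLD-1, against 12 for 2 and 10 Gy. Across lines the counts were 2323 at 2 Gy, 4431 at 10 Gy and 2506 at 5x2 Gy, and constant dye differences are part of all overlaps against control. Genes are not independent replicates, and these correlations carry no p-value.

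Lists that passed in none of the 13 comparisons included base and nucleotide excision and mismatch repair (lowest adjusted p = 0.28), the unfolded protein and amino acid stress list (0.44) and the NRF2 antioxidant list (0.11). Others were autophagy and lysosome (0.37), mesenchymal transition (0.17), enterocyte and goblet differentiation (0.23) and ERBB ligands and feedback (0.48), each with its lowest adjusted p over the comparisons. Of all 325 list tests, 64 passed, and 20 of these passed with an estimated correlation.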

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

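Of the tests in this part, only the counts of other splits, the test of intensity bias and the tests of slide and control RNA in the comparison of 5x2 Gy with 10 Gy were set before their results were seen. All others were chosen after. The interferon pattern took the place of a mitotic pattern, whose values stand in the report, after the values of both had been seen.

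HT29 and DLD-1 differed, by the test of the difference itself, in 903 genes after 2 Gy, 665 after 10 Gy and 1577 after 5x2 Gy. At 2 Gy and at 10 Gy no slide held both lines, so a slide difference cannot be told from a line difference there. Values are HT29 minus DLD-1 log2 ratios. After 2 Gy, PCGF1 (1.04), RHOD (0.88), JUNB (0.84), CHEK2 (0.60) and HYOU1 (0.56) were higher in HT29. FUT4 (-0.84), PPP1R12C (-0.87), BUB1 (-0.54), CENPE (-0.39), BARD1 (-0.42) and BRCA1 (-0.41) were lower. After 10 Gy, CCND1 (0.50) and BAG3 (0.61) were higher in HT29. BTG2 (-0.89), NR0B2 (-1.11), CXCL3 (-0.75), CENPE (-0.58), KIF20A (-0.52) and TAP2 (-0.52) were lower. After 5x2 Gy, IFI44L (2.24), MX1 (1.97), MX2 (1.85), IRF9 (1.54), TAP1 (1.30), PSMB9 (1.24) and CXCL10 (1.06) were higher in HT29. So were BBC3 (0.74), ANGPTL4 (1.31) and MSMO1 (0.71). MYBL2 (-1.04), PLK1 (-0.92), TOP2A (-0.60), RRM2 (-0.68) and PCNA (-0.50) were lower, as were CDKN1A (-0.74), THBS1 (-0.96) and ETS1 (-1.11).

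For every count of called genes, 1 split of the arrays, the real one, gave as many genes. Splits were too few for a share under 0.05. Against control there were 4 sign patterns of the 3 arrays, with real counts of 5325, 7330 and 6662 in DLD-1 at 2, 10 and 5x2 Gy and highest other counts of 3, 46 and 9. In HT29 the real counts were 4591, 6958 and 4294 and the highest other counts 12, 23 and 9. Between groups there were 10 splits of 6 arrays. For 10 Gy against 2 Gy the real and highest other counts were 41 and 0 in DLD-1 and 463 and 16 in HT29, and for 5x2 Gy against 10 Gy 3041 and 1 in DLD-1 and 1365 and 1 in HT29. For HT29 against DLD-1 they were 903 and 0, 665 and 9, and 1577 and 1 at 2, 10 and 5x2 Gy.

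Between 4294 and 7330 genes passed against control in each group, of which 118 rose and 919 fell in all 6. An intensity trend of the kind that loess removes was argued against as their source. A share of 0.893 of the genes so called under median centring kept those calls under loess. Bias that loess leaves would keep this share as high, so the share does not test it. A dye effect of single probes and a radiation response common to all doses stay open and cannot be told apart. Along the call, 10 Gy exceeded 2 Gy by a median of 0.0583 in DLD-1 and 0.1003 in HT29. A dye effect was set to give under 0.1 in both lines, which DLD-1 met and HT29 missed narrowly, and a dose response over 0.3, which neither met. By these limits, set after the data had been seen, the values lie on the side of a dye effect. The genes were chosen for passing at 2 Gy too, however, which can lower the difference. A response that does not grow with dose would also give such values. No dye swap was made, so dye and treatment lie on the same channel.

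The 5x2 Gy and 10 Gy arrays differed in 3041 genes in DLD-1 and 1365 in HT29. Control RNA that differed between those arrays stays open. For a share of 0.574 of the called genes in DLD-1 and 0.359 in HT29 the control channel moved more and against the ratio. The explanation needed over 0.5 in both lines, and HT29 fell short. Both channels can also shift together between these arrays, as the G1/S medians in HT29 did (-0.60 in Cy5, -0.58 in Cy3). Such a shift can raise the share, so it does not show how many calls came from control RNA. A slide effect stays open, as HT29 5x2 Gy replicate 3 on the slide of the DLD-1 5x2 Gy arrays departed from replicates 1 and 2 with r = 0.137 to the DLD-1 difference across called genes. A response to fractionation shared by the lines stays open too, with r = 0.345 across genes called in either line, and a shared shift of the control RNA would also give such an r. These explanations cannot be fully told apart, because 5x2 Gy shares no slide with 10 Gy in either line and control cultures were not set against each other on an array. In HT29, however, 2 Gy replicates 2 and 3 lay on the slide of 5x2 Gy replicates 1 and 2. The HT29 control channel differed in 0 genes between 10 Gy and 2 Gy, but in 3734 between 10 Gy and 5x2 Gy. That argues against the slide alone as the source of this channel's difference. Within the slide of those 4 arrays, 134 genes differed in the ratio between 5x2 Gy and 2 Gy.

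Interferon-stimulated genes lay higher after 5x2 Gy in HT29. A slide effect was argued against by 2 list medians within slides that together hold all 3 HT29 5x2 Gy arrays. Replicates 1 and 2 against 2 arrays of HT29 2 Gy gave 1.03, and replicate 3, 1 array that decides nothing alone, against the DLD-1 5x2 Gy arrays gave 1.26. Control RNA was argued against by a Cy5 median of 1.45 between 5x2 Gy and 10 Gy arrays, with 0.11 in Cy3. One aberrant array was argued against by the lowest of the 3 array medians, 0.81. An aberrant culture stays open, because the labels do not say whether the 3 arrays came from separate cultures. In DLD-1 the list did not pass after 5x2 Gy. Of its 40 genes 7 rose and 4 fell against control, where 2603 of all 15774 genes rose and 4059 fell. The rises were near the share over all genes, while the falls were fewer than that share. The list medians on the 3 DLD-1 5x2 Gy arrays were 0.04, 0.04 and 0.09, against -0.04 over all genes. A weaker response there is thus not excluded. A candidate explanation is a stronger response of HT29 to the fractions, a hypothesis found on the same data that no test here decides, while a difference in the time since the first fraction or in culture conditions of that group was not tested.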

How the results depend on the processing

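Among the alternatives here, median spot signals, keeping marked spots, setting a group against the mean of the 6 groups and using only arrays of 1 slide were chosen after the data had been seen, as was the slide block for gene lists. All others were planned. Unless said otherwise the cause of a change was not tested. Counts of called genes stayed within 1.5 times without background subtraction, without a filter on dim probes, with the mean of probes, with marked spots kept and with the deposited log2 values.

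Median centring gave 275 genes (463) for HT29 10 Gy against 2 Gy and 542 (903) for the lines at 2 Gy, with the count of the fit as designed in parentheses. Its splits of rises and falls were 4141 and 2816 (DLD-1 5x2 Gy), 2623 and 1919 (HT29 5x2 Gy), 3066 and 786 (DLD-1 5x2 Gy against 10 Gy), 295 and 207 (lines at 10 Gy) and 492 and 722 (lines at 5x2 Gy). Scale normalization gave 17 (DLD-1 10 Gy against 2 Gy), 273 (HT29 10 Gy against 2 Gy), 1446 (lines at 2 Gy) and 186 (lines at 10 Gy). Probes above background in both channels on all arrays, a filter that tests fewer genes, gave 2984, 4189 and 3651 for DLD-1 and 2786, 3928 and 1994 for HT29 at 2, 10 and 5x2 Gy against control, and 883 for HT29 5x2 Gy against 10 Gy. Genes called in the same direction were then 2352 (DLD-1 2 and 10 Gy), 1367 (2 and 5x2 Gy), 1720 (10 and 5x2 Gy), 1747 (HT29 2 and 10 Gy), 833 (2 and 5x2 Gy), 1191 (10 and 5x2 Gy), and 1199, 2508 and 1076 across lines at 2, 10 and 5x2 Gy. Only the arrays compared, with fewer degrees of freedom, gave 18 (DLD-1 10 Gy against 2 Gy), 8 (HT29 10 Gy against 2 Gy), 453 (HT29 5x2 Gy against 10 Gy), 469 (lines at 2 Gy) and 150 (lines at 10 Gy).

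The slide as a random block (correlation -0.083) gave 91, 743 and 2294 for DLD-1 and HT29 10 Gy against 2 Gy and HT29 5x2 Gy against 10 Gy, and 1614 for the lines at 10 Gy. As a fixed block, which rests on 1 array of 2 Gy or, for the lines, of HT29 5x2 Gy, it gave 0, 92 and 19 for the first 3 and 207 for the lines at 5x2 Gy, and within 1 slide, from the same 1 array, the counts were 0 and 102 for 10 Gy against 2 Gy and 216 for the lines at 5x2 Gy. For the 0 of limma, 881 and 931 genes had an unadjusted p under 0.05. Array weights gave 520, 5785, 2183 and 2757 for 10 Gy against 2 Gy and 5x2 Gy against 10 Gy in DLD-1 and then in HT29, and 3237 and 2524 for the lines at 10 and 5x2 Gy. Cy5 compared directly gave 7 (DLD-1) and 728 (HT29) for 10 Gy against 2 Gy, with 6 of 41 and 213 of 463 calls kept and 0 reversed. For 5x2 Gy against 10 Gy it gave 4291 (DLD-1) and 3072 (HT29), but kept only 825 of 3041 and 561 of 1365 calls and reversed 336 and 27. Median spot signals gave 252 (HT29 10 Gy against 2 Gy), 419 (lines at 2 Gy) and 1024 (lines at 5x2 Gy). Against the mean of the 6 groups, which removes what the groups share, DLD-1 had 234, 1627 and 2939 and HT29 1203, 958 and 1000 genes at 2, 10 and 5x2 Gy. Of all 325 list tests 64 passed, 20 of them also with an estimated correlation. With fry 124 of the 325 passed, a test that does not compare a list with other genes.

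Same-numbered replicates did not pair, with deviations correlated over 0.1 in 3 of 18 pairs (-0.137 to 0.148). The replicate block gave 35 (41) to 7197 (7330) genes as a fixed term and 41 to 7330 as a random term (correlation -0.003), within 1.5 times in every comparison. With the fixed replicate block 61 list tests passed, and histones (adjusted p = 0.056), repair (0.056) and ribosomal proteins (0.31) in DLD-1 at 2 Gy and oxidative phosphorylation between lines at 2 Gy (0.092) did not.

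Leaving out 1 array gave 3266 to 3808 (DLD-1 2 Gy, lowest without replicate 2), 4947 to 6213 (10 Gy) and 4613 to 5246 (5x2 Gy) genes against control. In HT29 it gave 2730 to 3368 (2 Gy, 2730 and 2799 without replicates 1 and 3), 4427 to 6289 (10 Gy, lowest without replicate 2) and 2612 to 2867 (5x2 Gy, 2642 and 2612 without replicates 2 and 3). For 10 Gy against 2 Gy the range was 2 to 39 in DLD-1 and 25 to 1215 in HT29. For 5x2 Gy against 10 Gy it was 1963 to 2419 in DLD-1, with 1963 without 10 Gy replicate 1 and 2022 without 5x2 Gy replicate 3, and 517 to 1653 in HT29. The report names the other arrays. Between lines it was 211 to 1008, 159 to 404 and 795 to 1486 at 2, 10 and 5x2 Gy. At 2 Gy the count was 385, 376 and 486 without DLD-1 replicates 1 to 3, and at 10 Gy 240, 311 and 159 without those of DLD-1 and 324, 404 and 184 without those of HT29.

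Of 206 named gene values, 3872 alternatives gave 3637 with the same direction and side of the threshold, 211 that no longer passed, 10 that newly passed and 14 with the other sign. CCNB1 in HT29 turned to 0.079 (2 Gy) and 0.23 (5x2 Gy) with median centring, and at 5x2 Gy to 0.066 with the mean of probes, 0.0083 with array weights and 0.033 without HT29 5x2 Gy replicate 1, with a range of -0.068 to 0.033 over the arrays left out. CDKN1A in HT29 at 2 Gy turned to 0.0016 with median spot signals. In Cy5 alone, which leaves out the control RNA, 5x2 Gy against 10 Gy gave MALAT1 0.084, MSMO1 0.53, P4HA1 0.78, ANGPTL4 1.33, ALDOC 1.94, FANCI -0.070 and CCN1 -0.41 in DLD-1 and MSMO1 0.48 in HT29. The scanner software's own log ratio was not run, as the files used here hold none, nor a fixed slide block for DLD-1 5x2 Gy against 10 Gy. Signal over background limits the weaker genes, as 51.1 to 72.6% of gene spots an array were above background in Cy3 and 42.9 to 65.3% in Cy5.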

Other observations

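Of 6 fibroblast markers, 0 were above background on all 18 arrays. Of 6 endothelial markers 1, CDH5, was above background on all arrays, of 6 leukocyte markers with a probe 1, CD14, and of 3 erythroid markers with a probe 1, HBA2. Short of all arrays, PTPRC and CD68 were above background on 17, VWF on 16 and ALAS2 on 15, so more than 1 marker of these classes gave signal on most arrays. No hypothesis was tested on these levels.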
